A study of Mus musculus with 3 samples.

How the data were processed

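Gene expression was measured by RNA sequencing in 3 libraries of mouse gastric corpus organoids, 1 per group: Mist1-, Mist1+ and Gpx4 KO-Mist1+. Per the labels, RNA was taken up in TRIZOL, its integrity number was read on a Bioanalyzer, and the libraries were run on an Illumina HiSeq instrument. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.1, aligned with HISAT2 2.2.1 to GRCm38.p5 and counted per gene with HTSeq 0.6.1. The deposited table holds 1 line per gene, 56691 in all. Per the file headers it gives for each library a count, which is a whole number of reads per gene, and an FPKM, which the authors derived from it. The deposited FPKM were checked against count divided by exonic length and by the column total. The largest deviation was 2.85% in Mist1-, 1.33% in Mist1+ and 1.58% in Gpx4 KO-Mist1+, over 11128, 11446 and 11633 genes with at least 50 counts. Raw reads were not analysed here, so trimming, alignment and counting are as the authors left them.

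The libraries held 14943918, 16187378 and 16396693 counts. For a transcript of 1000 bases, 3 counts correspond to an FPKM of 0.201, 0.185 and 0.183. The 10 most abundant genes took 7.93%, 7.64% and 8.47% of the counts, and Rn18s-rs5, a ribosomal RNA gene, took 1.22%, 0.635% and 0.585%. The FPKM columns summed to 379460, 302663 and 310243, so they are not on a common sum. Gene identifiers were matched to GENCODE M21 on GRCm38, which shares 52073 of them, and the coordinates of Gpx4 and Bhlha15 are from that release. The start and end in the table were the same as in M21 for 2.83% of the shared identifiers, so the annotation build behind the table is not known. The table has no biotype column. In it 2639 lines lack a symbol, and they hold at most 0.298% of the counts of a library; they stayed in the totals.

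Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Genes with an FPKM of at least 1 in at least 1 library were kept, 13351 in all. Log2 ratios were taken of FPKM plus a pseudocount of 1, and genes at least 2-fold apart were counted by direction for Mist1+ against Mist1-, for Gpx4 KO-Mist1+ against Mist1+, and for Gpx4 KO-Mist1+ against Mist1-. With 1 library per group no p-value was computed. Counts have exact Poisson 95% intervals, and folds of counts scaled to the column totals have exact 95% intervals from the binomial split of the 2 counts. Where a count was 0, the fold is given as at least the ratio to a floor of 3 counts. Genes set apart in 1 library were those at least 2-fold from both others while these lay within 1.5-fold of each other.

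Before the files were opened 35 gene lists were fixed. A list was compared if at least 4 members passed the filter, which held for 26 lists, and 9 had too few. The median log2 ratio of each list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and called outside below percentile 2.5 or above 97.5. This describes these libraries and is no test across animals. Genes were named by a rule fixed beforehand. It took Gpx4 and Bhlha15; the 10 highest and 10 lowest genes of both main comparisons with an FPKM of at least 5 in the higher library and a gene name; up to 4 members per list with the largest ratios; and the top 3 of each set-apart class. Because the table has no biotype, small RNAs entered by this rule, and the same ranks among genes that M21 calls protein-coding were added after the values were seen. Not every gene that the rule takes is reported here.

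The alternatives were pseudocounts of 0.1 and 5, no filter or an FPKM of at least 5, FPKM rescaled to a common sum (TPM), median ratio scaling, counts scaled to column totals without gene length (CPM), cutoffs of 1.5-fold and 4-fold, 5 expression bins, and bins of the mean over the 2 libraries compared. Each scaling had its own filter at a value of at least 1, which kept 16770 genes on TPM, 13333 with median ratio scaling and 14217 on CPM, so the gene set and the weight of the pseudocount changed along with the scaling. Between 2 libraries the length of a gene cancels, so before the pseudocount its CPM ratio was close to its FPKM ratio. Results on CPM thus differ from the main setting mainly through the pseudocount, the filter and the expression bins. A planned restriction by the table's own biotype could not be run as written. Added after the values were seen were protein-coding genes by M21 (11051 genes), log2 ratios with the trend on exonic length removed by lowess (fraction 0.3), and random lists matched on expression and exonic length in 10 by 10 bins, the last also for Gpx4 KO-Mist1+ against Mist1-. Pathways of 15 to 200 measured genes, 239 in all, were taken from the KEGG column of the deposited table after the values were seen. KEGG's main block of human disease maps was left out, but some maps named for a disease stand elsewhere and stayed in, such as non-alcoholic fatty liver disease, Type I and Type II diabetes mellitus and Cushing syndrome. Maps made for other organisms stayed in as well, and some processes have several maps, such as the Hippo signaling pathway and its fly version. The share of pathways with a positive rho between length and log2 ratio was set beside 2390 random gene sets of the same sizes, 10 per pathway.

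The steps were tested on simulated data built from the Mist1+ and Mist1- libraries. Of 100 genes with a log2 difference of 1.5, 100% were found at least 2-fold apart, as were 99% of 100 genes with a difference of 2 and 0.608% of 13151 genes with none, out of 13351. Lists of 12 genes without a difference were outside the random lists in 5% of cases, and lists shifted by 0.5 were above them in 100%. The genes given a difference were drawn among those with a mean FPKM of at least 5 over the libraries. The simulated counts held only Poisson counting error, with no trend on length and no variation between cultures. These percentages are thus not error rates for the real libraries.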

Results

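RNA from 3 cultures of mouse gastric organoids was sequenced, with 1 library in each of 3 groups. The title of each culture also carries the label P5. Organoids are epithelial structures grown from tissue cells inside a gel matrix, and these came from the stomach corpus, the acid- and pepsinogen-secreting part of the organ, and were kept in a medium for proliferation. The mice carried a Cre recombinase at the Mist1 locus with a red fluorescent reporter, so that cells with Mist1 activity could be marked. The Mist1- and Mist1+ cultures have a wild-type label, and the culture labelled Gpx4 KO-Mist1+ came from mice that also had a floxed Gpx4 gene. The libraries held 14943918 counts for Mist1-, 16187378 for Mist1+ and 16396693 for the one labelled Gpx4 KO-Mist1+. At least 1 count was found for 19758, 21624 and 21835 genes, in the same order. FPKM reached 1 for 11691, 12286 and 12371 genes. Mitochondrial genes took 3.57%, 4.26% and 5.14% of the counts. Xist had 1, 2 and 4 counts and the Y-linked gene Ddx3y had 883, 1670 and 1975, so all 3 libraries held Y-linked transcripts and almost no Xist. With 1 library per group no difference has a replicate check and no test across groups was possible; every comparison describes these libraries. Folds are ratios of counts scaled to the column totals, with 95% intervals for counting error only. Log2 ratios and the 2-fold calls add 1 to each FPKM, so a gene with low values can pass 2-fold in its counts and not in its call.

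Gpx4 encodes the glutathione peroxidase that reduces lipid hydroperoxides in membranes and holds back ferroptosis, an iron-dependent form of cell death. It was not lower in the library labelled as its knockout than in Mist1+, though it was lower there than in Mist1-. Gpx4 (ENSMUSG00000075706) stands at chromosome 10, 80047166 to 80056439, plus strand, in GRCm38. Its counts were 4399 in Mist1-, 1998 in Mist1+ and 2569 in the library labelled Gpx4 KO-Mist1+. The FPKM values were 171 (166 to 176), 71.6 (68.5 to 74.8) and 90.9 (87.4 to 94.5). Relative to Mist1+, the level in the labelled knockout was 1.27-fold (1.20 to 1.35), a log2 ratio of 0.34. A count over the whole gene includes reads from any exons that a deletion leaves in place, so it is not a check of the deleted part, and the label is kept here only as a label. Bhlha15 (ENSMUSG00000052271), the gene for Mist1, a transcription factor of secretory cells, stands at chromosome 5, 144190286 to 144194441, plus strand. It had 282, 580 and 370 counts. Its FPKM was 5.40 (4.79 to 6.07) in Mist1-, 10.2 (9.44 to 11.1) in Mist1+ and 6.46 (5.82 to 7.15) in the library labelled Gpx4 KO-Mist1+. Bhlha15 was thus 1.9-fold (1.64 to 2.2) higher in Mist1+ than in Mist1-.

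**Figure D1:**
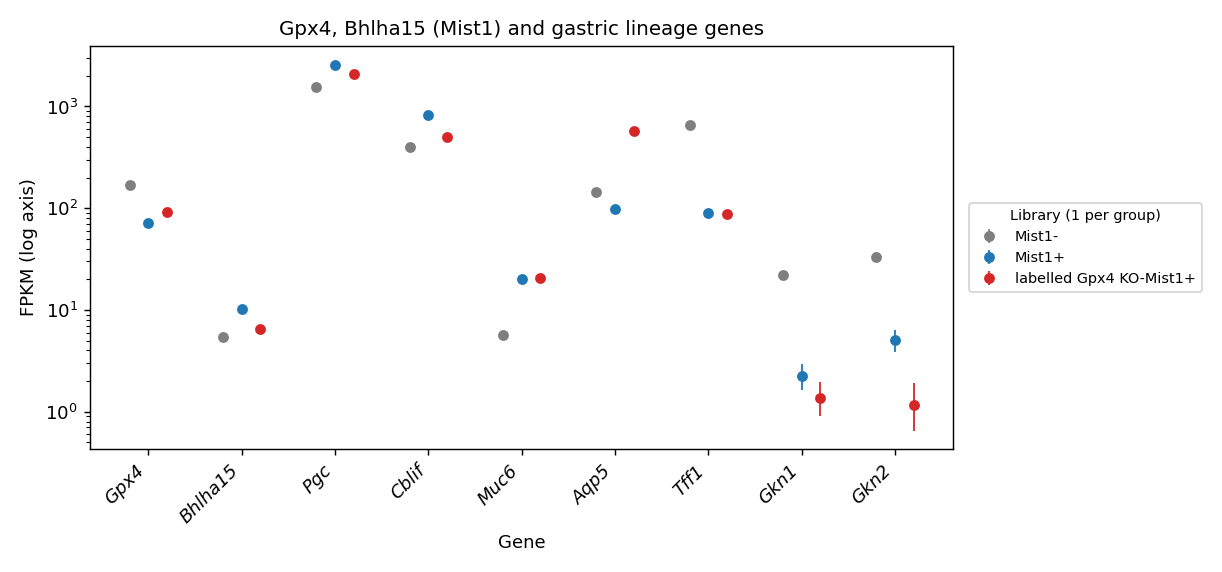
FPKM (log axis) of Gpx4, Bhlha15 and 7 gastric lineage genes, 1 point per library, with bars for the 95% Poisson interval of the counts. Tff1 was at 657 in Mist1- and at 90.6 and 87.7 in the other libraries, while Aqp5 was at 568 in the library labelled Gpx4 KO-Mist1+ and at 146 and 97.2 in Mist1- and Mist1+.

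The comparison of Mist1+ with Mist1- asks how organoids from cells with Mist1 activity differ from those without it. Genes of chief cells, the pepsinogen-secreting cells of the corpus gland, were higher in the Mist1+ library, and some genes of surface pit cells, which line the mucosa, were lower. Intrinsic factor, Cblif, was at 823 FPKM in Mist1+ and 403 in Mist1-, which is 2.04-fold higher (1.99 to 2.09), and pepsinogen C, Pgc, was at 2579 and 1539, or 1.68-fold higher (1.65 to 1.70). Among pit cell genes the trefoil factor Tff1 was 7.25-fold lower (6.79 to 7.75), and the gastrokines Gkn1 and Gkn2 were 9.97-fold (7.31 to 13.9) and 6.67-fold (5.11 to 8.83) lower. Hypoxia and glycolysis genes were lower as a group.

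Of the 8 chief cell genes in the list only 4 passed the filter (Cblif, Bhlha15, Pgc and the secretory granule gene Rab3d), and all 4 had a log2 ratio above 0. Their median was 0.78, at percentile 99.97 of random lists matched on expression; the list holds Bhlha15 itself. Of 13 stem and isthmus genes 10 were above 0, with a median of 0.60 and percentile 99.84. Iqgap3 was 2.81-fold higher (2.59 to 3.06), Lrig1 1.94-fold (1.83 to 2.05) and the Wnt target Axin2 2.05-fold (1.75 to 2.41), whereas Ascl2 was 2.31-fold lower (1.66 to 3.25). On counts scaled to column totals without gene length (CPM) this list was no longer outside the random lists. Gene length cancels between 2 libraries, so this setting mainly changed the weight of the pseudocount, the filter and the expression bins. Of 8 pit cell genes 3 were at least 2-fold lower, Tff1, Gkn1 and Gkn2, with a median of -0.70 and percentile 2.40, close to the cutoff; the list was inside the random lists on CPM, with a pseudocount of 0.1, without a filter and with length matched. Mucous neck cell genes went both ways, with Muc6 3.49-fold (3.29 to 3.71) and A4gnt 2.66-fold (2.35 to 3.02) higher and Tff2 3.39-fold lower (3.06 to 3.76), and their median was -0.52.

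Of 15 hypoxia and glycolysis genes 9 were at least 2-fold lower in Mist1+ and none at least 2-fold higher, with a median of -1.10, below all 10000 random lists. Carbonic anhydrase Car9 was 2.94-fold (2.71 to 3.18), the prolyl hydroxylase gene Egln3 2.91-fold (2.66 to 3.19) and adrenomedullin, Adm, 5.04-fold (3.08 to 8.62) lower. Glutathione peroxidases and transferases other than Gpx4 had a median of -0.83 at percentile 0.620, with 4 of 18 at least 2-fold lower. Gstp1 was 2.44-fold (2.34 to 2.54) and Gpx1 2.12-fold (1.99 to 2.26) lower; Gsta1 and Gsta2 were 3.47-fold and 3.95-fold lower but are near-identical copies, so their counts are uncertain. NF-kB targets and chemokines had a median of -0.47 at percentile 0.700, with Il33 2.63-fold (2.41 to 2.86) and Cxcl5 2.31-fold (2.15 to 2.48) lower. Fatty acid synthesis genes were above the random lists, with a median of 0.36 at percentile 98.7 and 12 of 13 above 0, but inside them on CPM, without a filter and with length matched (percentile 58.5). The synthase Fasn was 2.11-fold (2.03 to 2.2) and acetyl-CoA carboxylase, Acaca, 2.07-fold (1.9 to 2.26) higher.

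These differences went with gene length. Across 13351 genes with FPKM of at least 1 in some library, the Spearman rho between exonic length and log2 ratio was 0.49, and genes are not independent replicates. With genes put in 5 equal groups by length, in the shortest group (median 672 bases) 361 were at least 2-fold higher and 546 lower in Mist1+, and in the longest (median 9234 bases) 487 were higher and 1 was lower. Ribosomal protein genes other than Rpl29 were all lower in Mist1+ than in Mist1-, 71 of 71 under each scaling, with a median of -1.34 (range -1.76 to -0.79), or -0.96 with the length trend removed; they have many processed copies, so single counts are uncertain. Against random lists matched on length as well, chief cell genes (percentile 99.98), stem and isthmus genes (99.19) and hypoxia and glycolysis genes (0) were still outside. The pit cell list (18.2), the glutathione list (4.50), the NF-kB list (5.93) and the fatty acid list (58.5) were not. With the same matching, ferroptosis defence genes were below (percentile 2.13), with a median of -0.03 beside 0.23 for the random lists. Mitochondrially encoded genes (99.975) were above, though their median was -0.14, because that of the random lists was -0.86. Immediate-early and heat shock genes (98.9) were above too, at 0.14 beside -0.23. Mitochondrial genes share sequence with nuclear copies, so their counts are uncertain.

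**Figure D2:**
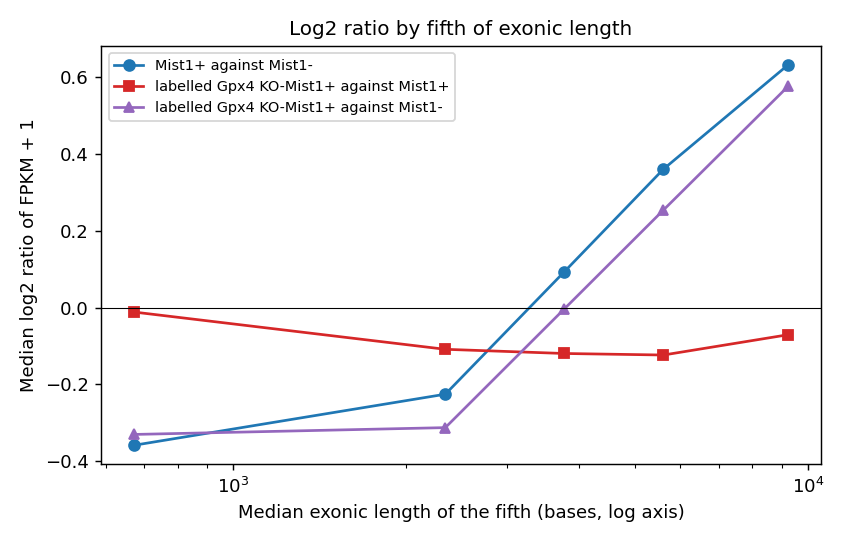
Median log2 ratio of FPKM + 1 in each of 5 equal groups of genes by exonic length (log axis, bases), 1 line per pair of libraries. For Mist1+ against Mist1- the median went from -0.36 in the shortest group to 0.63 in the longest, while for the library labelled Gpx4 KO-Mist1+ against Mist1+ it went from -0.01 to -0.07.

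In all, 1052 genes were at least 2-fold higher and 765 at least 2-fold lower in Mist1+ than in Mist1-. The split was 3795 to 673 with FPKM rescaled to a common sum (TPM), 1594 to 680 on CPM, 737 to 1065 after median ratio scaling, 129 to 396 with a pseudocount of 5 and 807 to 318 with the length trend removed. The first 3 of these also differ in the genes that pass the filter, 16770, 14217 and 13333, and in the weight of the pseudocount. For TPM and median ratio scaling, the effect of scaling alone was thus not separated. On CPM the ratios before the pseudocount were close to those of FPKM, so that change came mainly from the pseudocount and the filter. The median log2 ratio was 0.15 over the 13351 genes and 0.45 over the 16770 that pass on TPM. Beside the pit cell genes, the lowest protein-coding genes in Mist1+ were the surface antigen gene Ly6a (7.12-fold, 6.30 to 8.07), the cell cycle inhibitor gene Cdkn2a (9.14-fold, 6.02 to 14.4), S100a6 (5.02-fold, 4.71 to 5.36) and Phgr1 (5.09-fold, 3.91 to 6.70). The highest were Zbed6 (24.4-fold, 18.3 to 33.2), Pdpr (14.9-fold, 10.9 to 20.8), the kinase gene Hipk2 (11.8-fold, 9.52 to 14.7), Fam83b (9.72-fold, 7.50 to 12.8), Ppp1r3a, a glycogen-targeting subunit of protein phosphatase 1 (6.48-fold, 5.74 to 7.34), and Pik3c2a (6.18-fold, 5.68 to 6.72). Zbed6 lies inside another gene, Zc3h11a, so its count is uncertain. The named-gene rule also took small RNAs: mt-Tc, Mir6236 and Mir703 among the lowest and Mir186, Mir6386 and a pair of U6 rows among the highest, such as mt-Tc with 10 counts in Mist1- and 0 in Mist1+.

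The other 19 lists lay inside the range of the random lists for Mist1+ against Mist1-. Their medians were 0.67 for sex-linked genes, 0.36 for parietal cells, 0.33 for the interferon response, 0.25 for iron handling, 0.19 for Wnt targets, 0.14 for immediate-early and heat shock genes, 0.11 for proliferation and 0.09 for p53 targets. They were 0.01 for ferroptosis-promoting genes, -0.01 for cholesterol synthesis, -0.03 for ferroptosis defence, -0.06 for spasmolytic polypeptide-expressing metaplasia, -0.08 for YAP targets and regenerative genes, -0.14 for mitochondrially encoded genes and -0.21 for antigen presentation. Selenoproteins other than Gpx4 had -0.23, the unfolded protein and integrated stress response -0.26, NRF2 targets -0.48 and mucous neck cells the -0.52 given above. The sign turned under another scaling for the medians of immediate-early and heat shock genes, proliferation, p53 targets, ferroptosis-promoting genes, cholesterol synthesis, ferroptosis defence, metaplasia, YAP targets, mitochondrially encoded genes, selenoproteins and the unfolded protein response.

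The comparison of the library labelled Gpx4 KO-Mist1+ with Mist1+ asks what loss of Gpx4 does in Mist1+ organoids; since Gpx4 counts were not lower, its directions belong to the label only. As lists, genes of hypoxia and glycolysis, of the mucous neck and metaplastic lineages, Wnt targets and p53 targets were higher in the labelled knockout. The lists of proliferation and chief cell genes were lower. Against the other wild-type library, Mist1-, chief cell genes were not lower, with a median of 0.27 and 3 of 4 above 0, and proliferation genes had a median of -0.68 at percentile 2.76, inside the random lists; this pair has a length trend (rho 0.39), and with length matched too chief cell genes were above the random lists (97.89) and proliferation genes below (0.03). Transferrin, Trf, the iron carrier, was at 1045 FPKM against 27.2, or 38.4-fold higher (36.5 to 40.5). The water channel gene Aqp5 was 5.85-fold (5.66 to 6.05), Cd44 3.80-fold (3.66 to 3.95) and the stem cell receptor gene Lgr5 3.39-fold (3.22 to 3.57) higher. Of 20 proliferation genes none had a log2 ratio above 0.

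Of 15 hypoxia and glycolysis genes 13 were at least 2-fold higher, with a median of 1.71, above all 10000 random lists. Adm was 36.3-fold (23.3 to 59.7), Egln3 13.5-fold (12.5 to 14.7), Car9 12.8-fold (11.9 to 13.8) and Ndrg1 12.4-fold (11.2 to 13.7) higher. The same list was low in Mist1+ relative to Mist1-, but against Mist1- its median in the library labelled Gpx4 KO-Mist1+ was still 1.17. Of the 15 genes 14 were highest in that library and 13 lowest in Mist1+.

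**Figure D3:**
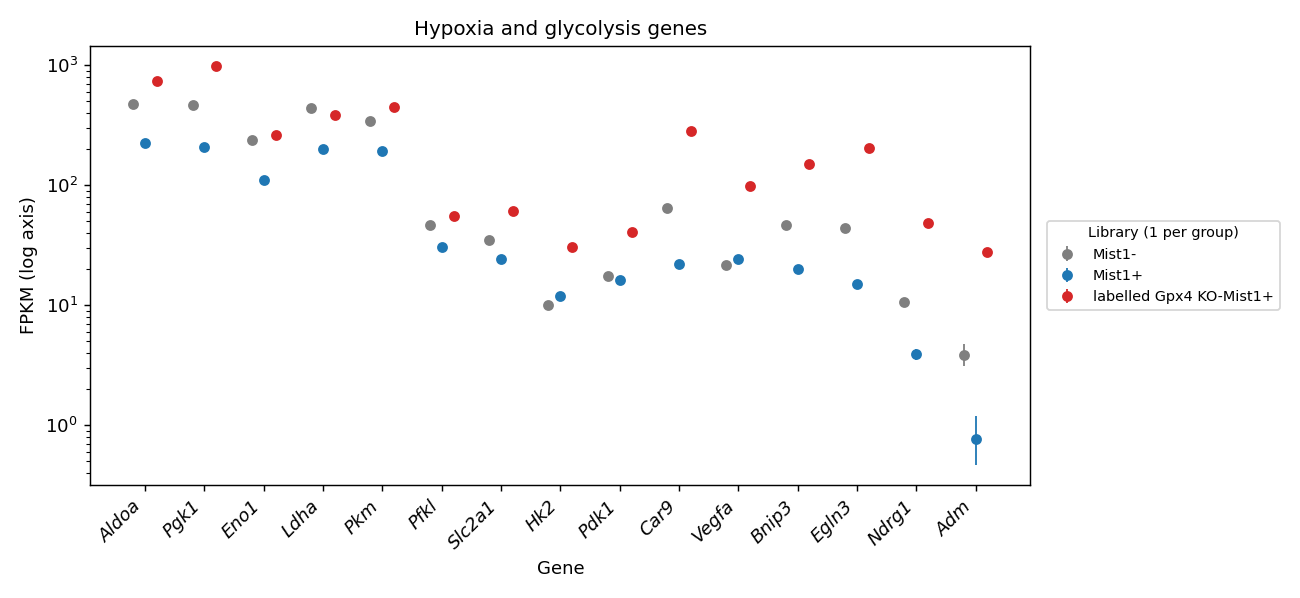
FPKM (log axis) of the 15 hypoxia and glycolysis genes, 1 point per library, with bars for the 95% Poisson interval of the counts. Of these genes 14 were highest in the library labelled Gpx4 KO-Mist1+ and 13 were lowest in Mist1+, as for Car9 at 64.8 (Mist1-), 22.1 (Mist1+) and 283 (labelled knockout).

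Of 14 genes of spasmolytic polypeptide-expressing metaplasia, a mucous lineage that appears in the injured corpus, 9 were at least 2-fold higher in the labelled knockout, with a median of 1.09 above all random lists. Beside Aqp5 and Cd44, the cystine transporter gene Slc7a11 was 3.32-fold (3.11 to 3.54) and Olfm4 3.25-fold (2.80 to 3.79) higher. Clu, also in that list, was 1.52-fold lower (1.51 to 1.53), at 4924 FPKM in Mist1+ and 3246 in the labelled knockout. Of 6 mucous neck cell genes 4 were at least 2-fold higher (median 1.07, percentile 99.99), and Aqp5, Gkn3 and Tff2 stand in both lists. Glipr1 was 2.53-fold (2.21 to 2.91), and Gkn3 2.11-fold (2.06 to 2.17) higher. The mucin gene Muc6 was at 20.6 FPKM against 20 in Mist1+, and A4gnt was 1.61-fold lower (1.45 to 1.78). All 4 measured chief cell genes were lower, with a median of -0.65 at percentile 0.570 (inside the random lists when no filter was used): Rab3d 1.94-fold (1.86 to 2.03), Cblif 1.64-fold (1.60 to 1.68), Bhlha15 1.59-fold (1.39 to 1.81) and Pgc 1.24-fold (1.22 to 1.25).

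Wnt targets had a median of 1.08 above all random lists, with 6 of 12 at least 2-fold higher. Nkd1 was 6.01-fold (4.17 to 8.91), Ascl2 3.66-fold (2.70 to 5.03) and Tnfrsf19 2.75-fold (2.62 to 2.89) higher. Lgr5, Axin2, Ascl2 and Tnfrsf19 are also in the stem and isthmus list, whose median was 0.03 and lay inside the random lists. Genes of YAP signalling and regeneration had a median of 0.39 at percentile 98.98, with 6 of 9 above 0. Ly6a was 13.7-fold (12.2 to 15.5), Ccn2 4.13-fold (3.91 to 4.38) and the growth factor gene Areg 3.86-fold (2.92 to 5.16) higher. Clu, also in this list, was lower, with a log2 ratio of -0.60. With a pseudocount of 5, or among genes with an FPKM of at least 5, the list was no longer outside. Of 20 proliferation genes 2 were at least 2-fold lower, with a median of -0.79 below all random lists. The replication helicase gene Mcm5 was 2.27-fold (2.14 to 2.42) and the mitotic kinase gene Plk1 2.21-fold (2.08 to 2.36) lower. Among p53 targets 14 of 15 were above 0, with a median of 0.72 above all random lists. The cell cycle inhibitor gene Cdkn1a was 3.80-fold (3.47 to 4.17), Gdf15 5.01-fold (3.75 to 6.79), Eda2r 3.32-fold (2.95 to 3.73) and Phlda3 2.16-fold (1.91 to 2.45) higher.

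Of 12 measured ferroptosis-promoting genes 4 were at least 2-fold higher and none at least 2-fold lower in the labelled knockout, with a median of 0.66 above all random lists. These were the transferrin receptor gene Tfrc (3.04-fold, 2.91 to 3.19), Chac1, which breaks down glutathione (8.97-fold, 5.82 to 14.5), the heme oxygenase gene Hmox1 (2.69-fold, 2.28 to 3.17) and Sat1 (2.26-fold, 2.13 to 2.39). Ferroptosis defence genes had a median of 0.13 at percentile 96.69, inside the random lists, and were at 98.56 with lists matched on length too. Slc7a11 and its partner Slc3a2, which form the cystine importer, led that list, with Slc3a2 2.15-fold higher (2.01 to 2.30). The unfolded protein and integrated stress response list had a median of 0.38 at percentile 99.93. In it Trib3 was 15.7-fold (10 to 26.1) and Nupr1 4.14-fold (3.29 to 5.25) higher, and Atf3 was 11.1-fold lower (9.15 to 13.6). The list of NF-kB targets and chemokines was at 0.22, percentile 98.49 (inside the random lists on CPM), with the siderophore-binding lipocalin gene Lcn2 15.9-fold (12.8 to 20) and Il33 6.53-fold (6.05 to 7.05) higher. Against Mist1- this list was inside the random lists, at percentile 81.97, but above with length matched too (98.66). The other 8 lists that were above relative to Mist1+ were above relative to Mist1- as well, but the ferroptosis-promoting list was inside once length was matched (97.06).

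**Figure D4:**
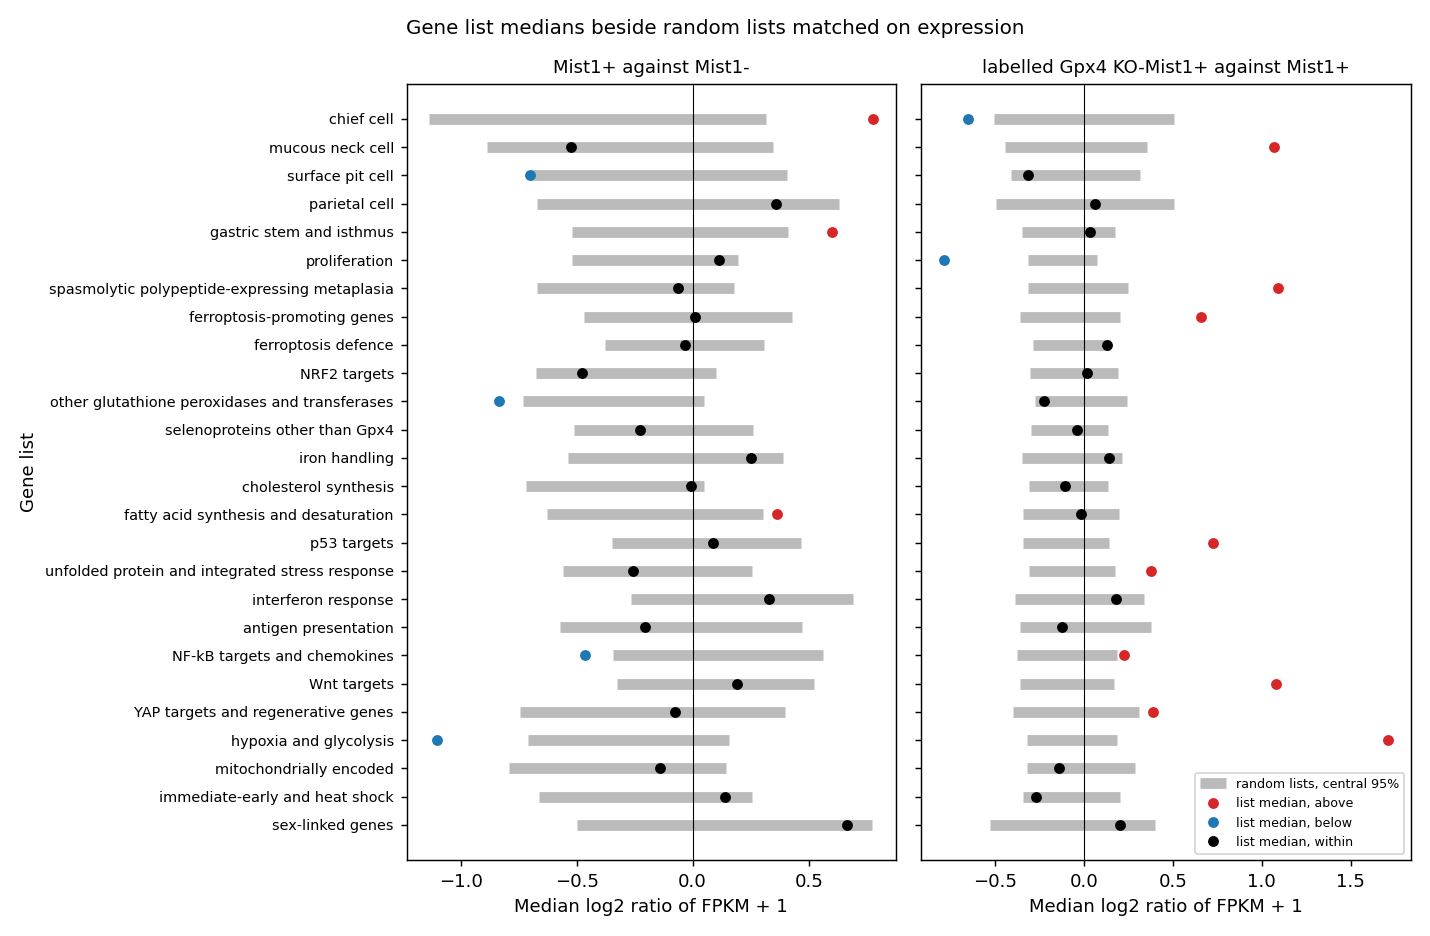
Median log2 ratio of FPKM + 1 for the 26 gene lists with at least 4 measured genes (points), with the central 95% of random lists matched on expression (grey bars), for both main pairs of libraries. In the right panel 9 lists lie above and 2 below their bar, and hypoxia and glycolysis is the farthest, at 1.71.

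In all, 642 genes were at least 2-fold higher and 366 at least 2-fold lower in the library labelled Gpx4 KO-Mist1+ than in Mist1+, and the Spearman rho with exonic length was -0.02. The numbers were 1348 and 1100 on TPM, over 16770 genes, and 1414 and 1514 at a cutoff of 1.5-fold, where more genes were lower than higher. Beside Trf, Adm, Ly6a, Egln3 and Car9, the highest genes included the endoplasmic reticulum oxidase gene Ero1a (22.3-fold, 21.3 to 23.4), the prostaglandin E synthase gene Ptges (4 and 786 counts, 194-fold, 75.5 to 714), Ly6d (22.6-fold, 12.7 to 44.3) and Cnfn. Cnfn had 242 counts against 0 in Mist1+, at least 79.6-fold higher against a floor of 3 counts. The lowest were the cholecystokinin receptor gene Cckar (24.3-fold, 20.3 to 29.5), chymosin, Cym (42.6-fold, 23.0 to 89.6), Atf3, Ppp1r3a (10.2-fold, 8.85 to 11.8), Clstn2 (16.2-fold, 11.4 to 23.7), Cyp2c65 (11.8-fold, 7.37 to 19.9), Emb (7.67-fold, 6.61 to 8.93) and the splicing factor gene Cwc22 (5.12-fold, 4.74 to 5.54). Rpl29 stood outside its family: it had 5584 counts in Mist1+ and 225 in the labelled knockout, a log2 ratio of -4.54. The 71 other ribosomal protein genes lay between -0.06 and 0.68, with a median of 0.39 and 70 of them above 0. Ribosomal protein genes have many processed copies, so the Rpl29 count is uncertain. A U6 row, with 18 counts and 1, was also among the lowest.

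In this comparison 15 lists lay inside the random lists. Their medians were 0.20 for sex-linked genes, 0.18 for the interferon response, 0.14 for iron handling, 0.13 for ferroptosis defence, 0.06 for parietal cells, 0.03 for stem and isthmus genes and 0.02 for NRF2 targets. They were -0.01 for fatty acid synthesis, -0.04 for selenoproteins other than Gpx4, -0.11 for cholesterol synthesis, -0.13 for antigen presentation and -0.14 for mitochondrially encoded genes. Other glutathione peroxidases and transferases had -0.23, immediate-early and heat shock genes -0.27 and surface pit cells -0.32. The medians of stem and isthmus genes, NRF2 targets, fatty acid synthesis, selenoproteins and cholesterol synthesis turned sign under another scaling.

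The remaining pair, the library labelled Gpx4 KO-Mist1+ against Mist1-, differs in both labels. It had 1553 genes at least 2-fold higher and 1143 lower, or 4076 and 998 on TPM and 349 and 564 with a pseudocount of 5. To place each library beside both others, genes were counted that were at least 2-fold apart from both while those lay within 1.5-fold of each other. In Mist1- 372 genes were set apart as higher, led by Tff1, Gkn1 and Spink4, and 513 as lower, with Mir186, 5S_rRNA and Pdpr at the top. In Mist1+ 98 were higher, led by Ppp1r3a, Thbs1 and Ern2, and 49 lower, led by Cdkn2a and the related copies Sprr2a1 and Sprr2a3. The library labelled Gpx4 KO-Mist1+ had 317 higher, led by Cnfn, Ptges and Mir7663, and 91 lower, led by Cym, Cyp2c65 and the colipase gene Clps. For Mist1- the balance turned to 530 higher and 377 lower with median ratio scaling and to 205 and 62 with a pseudocount of 5. That of Mist1+ turned to 15 and 18 with a pseudocount of 5, to 32 and 38 with an FPKM of at least 5 and to 31 and 36 among protein-coding genes. On TPM the numbers were 266 and 1821 in Mist1-, 441 and 86 in Mist1+ and 772 and 195 in the labelled knockout, over 16770 genes. The thrombospondin gene Thbs1 was at 62.5 FPKM in Mist1+, 18.9 in Mist1- and 13.7 in the labelled knockout. Cdkn2a was at 12.1 in Mist1-, 1.32 in Mist1+ and 10.7 in the labelled knockout.

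Markers of other cell types were scarce. In 9 of the 35 lists fewer than 4 genes reached 1 FPKM, and these lists were not compared. No gene reached 1 FPKM among the markers of enteroendocrine cells (highest 0.69, 0.85 and 0.65 in Mist1-, Mist1+ and the labelled knockout), fibroblasts and muscle (0.06, 0.06 and 0.11), endothelium (0.09, 0.07 and 0.12) and red blood cells (0.26, 0.08 and 0). Of 10 immune genes only the macrophage and lysosome gene Cd68 passed, at 4.37, 5.06 and 24.4 FPKM, and of 11 mesenchymal genes only Fn1, at 2.35, 5.31 and 4.04. The intestinal villin gene Vil1 was at 32.8, 14.2 and 85.0, the squamous gene Sprr1a at 22.1, 8.74 and 83.8, and the tuft cell gene Avil at 9.55, 5.00 and 17.4. These 3 genes were thus 6-fold (5.57 to 6.47), 9.60-fold (7.91 to 11.7) and 3.49-fold (3.05 to 4) higher in the library labelled Gpx4 KO-Mist1+ than in Mist1+. The other measured members of their lists did not all follow. In Mist1+ and the labelled knockout the intestinal genes Gpa33 and Fabp1 were at 5.75 and 15.8, and at 2.57 and 2.32 FPKM. The squamous genes Krt4 and Ivl were at 0.98 and 9.49, and at 1.45 and 2.28, and the tuft cell gene Ltc4s at 2.13 and 2.23.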

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

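There was 1 library per group. No paired analysis was possible because each group has 1 library and no pairing is given, leave-one-out was not possible for the same reason, and the planned restriction by the table's biotype was not run as planned. Of the alternatives, protein-coding genes by M21, the removed length trend and the length-matched random lists were chosen after the values were seen. Over all alternatives 827 values of the 197 genes that the naming rule takes moved and 1529 stayed the same, 63 counts moved and 105 stayed, and for lists 580 were the same, 18 stronger and 20 weaker. No list outside the random lists went to the opposite side. Some medians of lists inside the random lists changed sign. Of the 197 genes, the log2 ratio changed sign in at least 1 setting for 24 in Mist1+ against Mist1-, none of them above 0.56 in size in the main setting (Cd44, Clu and Clps among them), and for 12 in the library labelled Gpx4 KO-Mist1+ against Mist1+, none above 0.12 (Tff1, Muc6 and Pik3c2a among them). Why each value moved was not tested except where the setting itself fixes it, as for the cutoffs.

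Genes at least 2-fold apart, higher then lower, were 1052 and 765 for Mist1+ against Mist1-, 642 and 366 for the library labelled Gpx4 KO-Mist1+ against Mist1+, and 1553 and 1143 for it against Mist1-. In this order they were 1986 and 1130, 1028 and 773, and 2477 and 1622 with a pseudocount of 0.1. A pseudocount of 5 gave 129 and 396, 226 and 70, and 349 and 564, so that fewer genes were higher than lower in both pairs with Mist1-. An FPKM of at least 5 gave 649 and 616, 374 and 201, and 963 and 953. TPM, CPM and median ratio scaling each kept other genes (16770, 14217 and 13333), so scaling was not varied alone. CPM left the ratios before the pseudocount nearly as they were. TPM gave 3795 and 673, 1348 and 1100, and 4076 and 998. Median ratio scaling gave 737 and 1065, 752 and 277, and 1502 and 1236. CPM gave 1594 and 680, 822 and 459, and 2200 and 1160. Protein-coding genes by M21 gave 667 and 457, 443 and 204, and 1092 and 836. Removing the length trend gave 807 and 318, 597 and 394, and 1295 and 635. A cutoff of 1.5-fold gave 3165 and 2005, 1414 and 1514, and 3421 and 2689, and a cutoff of 4-fold gave 81 and 38, 120 and 31, and 165 and 76.

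For Mist1+ against Mist1-, 3 lists were above and 4 below in the main setting. Above and below were 3 and 3 with a pseudocount of 0.1, 2 and 3 without a filter, 1 and 5 on CPM, 2 and 4 with 5 expression bins, 4 and 3 with bins over the 2 libraries compared, 4 and 2 with the length trend removed and 4 and 2 with length-matched random lists. The surface pit cell list was lost with a pseudocount of 0.1, without a filter, on CPM, with bins over the 2 libraries and under both length settings. The fatty acid list was lost without a filter, on CPM, with 5 bins and under both length settings, the stem and isthmus list on CPM, and the glutathione and NF-kB lists under both length settings. Gained were NRF2 targets and selenoproteins below on CPM, proliferation above with bins over the 2 libraries, and, under both length settings, ferroptosis defence below and mitochondrially encoded and immediate-early genes above. For the library labelled Gpx4 KO-Mist1+ against Mist1+, 9 were above and 2 below in the main setting, and 11 and 1 without a filter, where the chief cell list was lost. The YAP list was lost with a pseudocount of 5 and with an FPKM of at least 5, and the NF-kB list on CPM. Ferroptosis defence was gained above in 6 settings (no filter, median ratio scaling, protein-coding genes, 5 bins and both length settings), iron handling above without a filter, and pit cells below with a pseudocount of 0.1 and with an FPKM of at least 5.

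Set-apart genes, higher then lower, were 372 and 513 in Mist1-, 98 and 49 in Mist1+ and 317 and 91 in the library labelled Gpx4 KO-Mist1+. A pseudocount of 0.1 gave 967 lower in Mist1-, 150 and 95 in Mist1+ and 219 lower in the labelled knockout. A pseudocount of 5 gave 205 and 62, 15 and 18, and 93 and 19, which turned the balance of Mist1- and of Mist1+. An FPKM of at least 5 gave 32 and 38 in Mist1+, which turned its balance, and 144 higher in the labelled knockout. TPM gave 266 and 1821 in Mist1-, 441 and 86 in Mist1+ and 772 and 195 in the labelled knockout. Median ratio scaling gave 530 and 377 in Mist1-, which turned its balance too. CPM gave 846 lower in Mist1-. Protein-coding genes gave 225 and 349 in Mist1-, 31 and 36 in Mist1+, where the balance turned too, and 206 and 62 in the labelled knockout. Removing the length trend gave 146 higher in Mist1- and 29 lower in Mist1+.

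The Gpx4 log2 ratio of Mist1+ over Mist1- was -1.24, and -0.92 on TPM, -1.40 with median ratio scaling and -0.72 with the length trend removed. For the labelled knockout over Mist1+ it was 0.34, and 0.46 with median ratio scaling. Bhlha15 in Mist1+ over Mist1- was 0.81, and 0.55 with a pseudocount of 5, 1.19 on TPM and 0.67 with median ratio scaling. For the labelled knockout over Mist1+ it was -0.59, and -0.41 with a pseudocount of 5.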

Other observations

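The KEGG pathways were chosen after the values were seen. Some processes have several maps, so the numbers of pathways are not numbers of separate results. Of 239 pathways, 46 lay above and 16 below the random lists for the library labelled Gpx4 KO-Mist1+ against Mist1+. Glycolysis / Gluconeogenesis had a median log2 ratio of 0.65, with 19 of 69 genes at least 2-fold higher, and HIF-1 signaling 0.27, with 25 of 111. ECM-receptor interaction had 0.41, cytokine-cytokine receptor interaction 0.27 and the Ferroptosis pathway 0.15 at percentile 99.89, with 9 of 44 genes at least 2-fold higher. The p53 and Wnt signaling pathways were above the random lists too, but with small medians. The p53 signaling pathway had 0.03 (percentile 99.24), with 8 of 75 genes at least 2-fold higher and 4 lower. The Wnt signaling pathway had -0.003 (percentile 98.3), with 6 of 103 genes at least 2-fold higher and 1 lower. Below were DNA replication at -0.64, linoleic acid metabolism at -0.53, mismatch repair at -0.36, ribosome biogenesis at -0.35, the spliceosome at -0.32 and the cell cycle at -0.28.

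For Mist1+ against Mist1-, 86 pathways lay above and 34 below, and 32 and 34 with random lists matched on length as well. Oxidative phosphorylation was at -0.89 with 64 of 160 genes at least 2-fold lower, the proteasome at -0.66 and Glycolysis / Gluconeogenesis at -0.38. The medians of their length-matched random lists were -0.55, -0.25 and -0.05, so much of the first shift was shared by genes of like length and expression. Each pathway was still below those lists, at percentile 0. Gastric acid secretion was at 0.39 and the tight junction at 0.33, both also above the length-matched lists, at percentiles 98.25 and 99.9. The parietal cell list, however, was inside the random lists, at percentile 83.5, or 90.5 with length matched. Of its 11 genes 5 were measured, with Atp4a at 1.03 FPKM in Mist1- and 1.69 in Mist1+. Among the genes set apart in Mist1+, Ern2, an endoplasmic reticulum stress sensor of mucous cells, was at 60.1 FPKM against 19.4 in Mist1- and 14.4 in the labelled knockout. The share of mt-Co1 was 1.40% in Mist1-, 1.82% in Mist1+ and 3.06% in the labelled knockout, while the other mitochondrial genes did not all follow it: mt-Nd5 was at 684, 2079 and 1791 FPKM.

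All 3 tests of the Gpx4 level, and for the hypoxia genes those of a low level in Mist1+ alone and of other culture differences, were chosen only after the result was seen; the tests of depth, length-dependent recovery and the length trend in the hypoxia genes were written before.

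Gpx4 was not lower in the library labelled Gpx4 KO-Mist1+ than in Mist1+. Scaling is argued against, since the lowest log2 ratio over the alternatives was still 0.31. A swap among the libraries was to show as 1 library with Gpx4 at least 2-fold below the next lowest. None was: Mist1+ had the lowest Gpx4 CPM, at 0.788 of the next lowest, the labelled knockout. A swap of Mist1+ with the labelled knockout still stays open, since partial transcripts would hide a loss. Mist1+ was also 2.38-fold lower than Mist1-, a pair with a trend on length (rho 0.49). Bhlha15 is the locus that carries the Cre, and what this does to its counts was not examined. The Mist1+ and Mist1- labels themselves go with Bhlha15, at 10.2 and 5.40 FPKM. They go with the chief cell genes too, of which all 4 measured were higher in Mist1+, but Bhlha15 is 1 of these. The labelled knockout, also named Mist1+, had Bhlha15 at 6.46 FPKM, closer to Mist1- than to Mist1+. Transcript kept outside the deleted exons, or cells with an intact allele, also stays open, since the whole-gene ratio of 1.27 cannot separate exons. Counts per exon of Gpx4, or a genotype of each culture, would settle it.

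Genes higher in Mist1+ than in Mist1- were longer. A difference in depth is argued against by the depths themselves, at 14943918 counts in Mist1- and 16187378 in Mist1+. The rho was still 0.49 after Mist1+ was thinned, but so small a thinning could hardly have moved it. Length-dependent recovery of RNA in the Mist1- library stays open, as does biology that favours long genes. The test for it, a positive rho within pathways, decides nothing: 98.3% of pathways passed, but so did 99.3% of 2390 random gene sets of the same sizes, a comparison added after the result was seen. A repeat library of Mist1- with its integrity number would separate these.

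Hypoxia and glycolysis genes were higher in the library labelled Gpx4 KO-Mist1+ than in Mist1+. The trend on length is argued against by the rho of -0.02 between length and log2 ratio in this pair. With so little trend to remove, the median of 1.74 after its removal adds no separate evidence. A low level in Mist1+ alone is argued against as a full account by the median of 1.17 against Mist1-. Differences between cultures that have nothing to do with Gpx4, such as density or oxygen at harvest, stay open, because the wild-type libraries themselves differed by -1.10. Replicate cultures harvested at matched density would show how much of it goes with the label.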
